A study of Bos taurus with 65 samples.

How the data were processed

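The deposited data were RNA-seq read counts from granulosa cells and theca tissue of the bovine dominant follicle. Granulosa cells line the inside of the follicle and theca cells surround it. Per the labels' protocols, polyadenylated RNA was sequenced as single reads on an Illumina instrument. The series held 65 libraries from 33 Holstein-Friesian animals, 16 lactating cows and 17 heifers that had not calved. Each of 32 animals gave a granulosa and a theca library, and heifer 3700 gave theca only here. Per the labels' protocols, oestrous cycles were synchronised with an intravaginal progesterone device, and each animal was slaughtered at 1 of 3 stages. Animals of the Selected stage were slaughtered on day 14 of the cycle, with a newly chosen dominant follicle and a corpus luteum. Differentiated animals were given prostaglandin and were slaughtered on day 16, 24 to 30 h after removal of the device and before oestrus. Luteinized animals received 5 ml of GnRH 30 h after removal, which induces a gonadotrophin surge, and were slaughtered on day 17, 18 to 22 h after GnRH and before ovulation. Stage and day of slaughter therefore went together, so each stage comparison also compares treatments and days.

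The authors deposited whole-number counts of reads per Ensembl bovine transcript, 28054 transcript identifiers per library, with no further normalization. The submitters' processing notes name CASAVA 1.0. The aligner, the counting tool, the genome build, the annotation release and the treatment of reads shared between transcripts are not given in the sources used here. Of the 22526 transcripts with at least 1 read in any library, 1343 (5.96%) had counts equal to those of another identifier in all 65 libraries, so transcripts of this kind cannot be told from each other. The files do not pair transcript identifiers with gene names, and 0 identifiers matched the names table used here. The fixed gene lists and cell type markers were therefore not tested, and transcripts are given by their identifiers alone. No coordinates are given for the same reason.

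Library totals ran from 2426969 to 6021423 counts in granulosa and from 1391286 to 9561195 in theca. Low transcripts in the shallowest theca library, from Differentiated cow 682.2, carry the largest counting error. Confidence intervals on pooled counts cover counting error only, since reads without molecular identifiers are not independent molecules. No library pair within a group agreed within sampling noise, the lowest chi-square per transcript for a pair being 3.22, so no pair looked like 1 library deposited again.

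Each tissue was fitted with edgeR 4.0.16 in R 4.3.3, using TMM normalization, the default filter on low counts by group, and the quasi-likelihood test on a design with 1 mean per stage and animal type. The filter left 14297 transcripts in granulosa and 15362 in theca. Contrasts compared successive stages averaged over cows and heifers, cows with heifers at each stage and averaged over stages, and the interaction of animal type with stage as a joint test. Granulosa and theca were compared in 1 fit over all 65 libraries with 15801 transcripts and 1 mean per tissue, stage and animal type. Calls are Benjamini-Hochberg adjusted p below 0.05, over the transcripts of a fit. All log2 fold changes come from these fits, and their standard errors were derived from the fitted fold change and its F statistic. Levels are CPM, counts scaled by the library total, with SD across animals. Named transcripts are those with the largest rise and fall among calls with a mean of at least 5 CPM over the libraries of the fit, up to 2 in each direction, and the part of the rule that asked for a gene symbol could not be applied.

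Granulosa and theca libraries carrying the same animal number come from the same animal. The correlation of their deviations from the group means had a median of 0.23 over 32 animals (range -0.18 to 0.59), against -0.06 for other animals of the same group. Because deviations were taken from group means, the value for other animals follows largely from the first and is not separate evidence. Of 32 granulosa libraries, 24 correlated best with the theca of their own animal. Fits with animal as a block were run for granulosa against theca, averaged over stages and at each stage, and for the interactions of tissue with stage; the tissue-biased sets were chosen without the block.

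Tissue-biased sets were transcripts at least 4-fold higher in 1 tissue at adjusted p below 0.05, chosen, for the stage contrasts, at the stage that did not enter the contrast. For the cow and heifer calls in theca at Selected they were chosen at Selected itself, and again at each later stage. They were tested with camera (limma 3.58.1) with a preset inter-transcript correlation of 0.01 and again with the correlation estimated from the data, adjusted over 8 tests. The share of counts in the 10 most abundant transcripts, the number of transcripts detected at a common depth of 1300000 counts and the median absolute log2 difference between the libraries of an animal were compared between stages with permutation tests of 100000 resamples, adjusted over 10 tests. These measures and sets left out the 559 transcripts near 0 in 6 granulosa libraries that the report describes.

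The fits were tested on simulated counts drawn with the real transcript means, dispersions and totals, with 200 transcripts changed by known folds. Transcripts were drawn independently of each other, so correlation between transcripts was not reproduced. Only transcripts above a minimum mean level were changed, so recovery of lower ones was not tested. For granulosa Luteinized against Differentiated, on 14297 transcripts, 38 of 50 changes of 2-fold and 50 of 50 of 4-fold were called, and 7 of 162 calls were false. For theca Luteinized against Differentiated, on 15362 transcripts, 49 of 50 changes of 2-fold were called and 7 of 196 calls were false. For theca Differentiated against Selected, 50 of 50 changes of 2-fold were called, and 14 of 203 calls (6.90%) were false. For cows against heifers at Selected, 25 of 50 changes of 2-fold and 46 of 50 of 4-fold were called in granulosa on 14297 transcripts, and 42 of 50 of 2-fold and 50 of 50 of 4-fold in theca on 15362. For theca of cows against heifers at Differentiated, 37 of 50 of 2-fold were called, and 10 of 170 calls (5.88%) were false. For cows against heifers at Selected the simulation gave 4 false calls in each tissue. Other splits of the real libraries gave a median of 0 calls there, but up to 676 in granulosa and 773 in theca. The simulated recovery and false calls may therefore be too favourable for the real libraries. The adjusted p also depends on how many transcripts change. More than 200 were called in each real stage contrast, so the simulated cut on p was stricter there. Recovery for the stage contrasts may thus err in either direction.

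The samples, tests and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0 (Wald test, likelihood ratio test for the interaction of animal type with stage), no filter, the suffix of the animal number as a covariate, a fit of only the groups compared, animal as a block, and leaving out each animal. Added after the data were seen were the 6 granulosa libraries as a covariate, those 6 left out, the 559 transcripts left out, heifer 3700 left out, and, for the tissue-biased sets, an estimated correlation, no filter, a filter on the stage outside the comparison alone and the 6 granulosa libraries left out. All alternatives for the tissue calls at each stage and for the calls shared by both tissues were also added then.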

Results

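Gene expression was measured in granulosa cells and in theca tissue of the dominant follicle at 3 stages, in cows and in heifers. Granulosa libraries came from 5 cows and 5 heifers at Selected, 7 cows and 5 heifers at Differentiated, and 4 cows and 6 heifers at Luteinized. Theca libraries came from the same animals and 1 further heifer at Selected, making 6. Granulosa totals had a median of 4249203.5 counts and theca totals a median of 6221356. The number of transcripts with at least 1 read ran from 15781 to 17699 per granulosa library and from 15970 to 18722 per theca library.

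The main axis of library structure set the Luteinized stage apart in both tissues, while Selected and Differentiated libraries overlapped along it. The first principal component held 56.8% of the variance in granulosa and 27.0% in theca, and it separated every Luteinized library from the libraries of the earlier stages. The most abundant transcript was ENSBTAT00000017420 in all 33 theca libraries. In granulosa it was ENSBTAT00000013154 in 26 libraries and ENSBTAT00000003783 in 6. The median coefficient of variation of a transcript between animals was 28.2% in granulosa and 19.3% in theca, and the common value over all transcripts, which include those lacking in 6 granulosa libraries, was 37.7% and 21.6%.

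**Figure D1:**
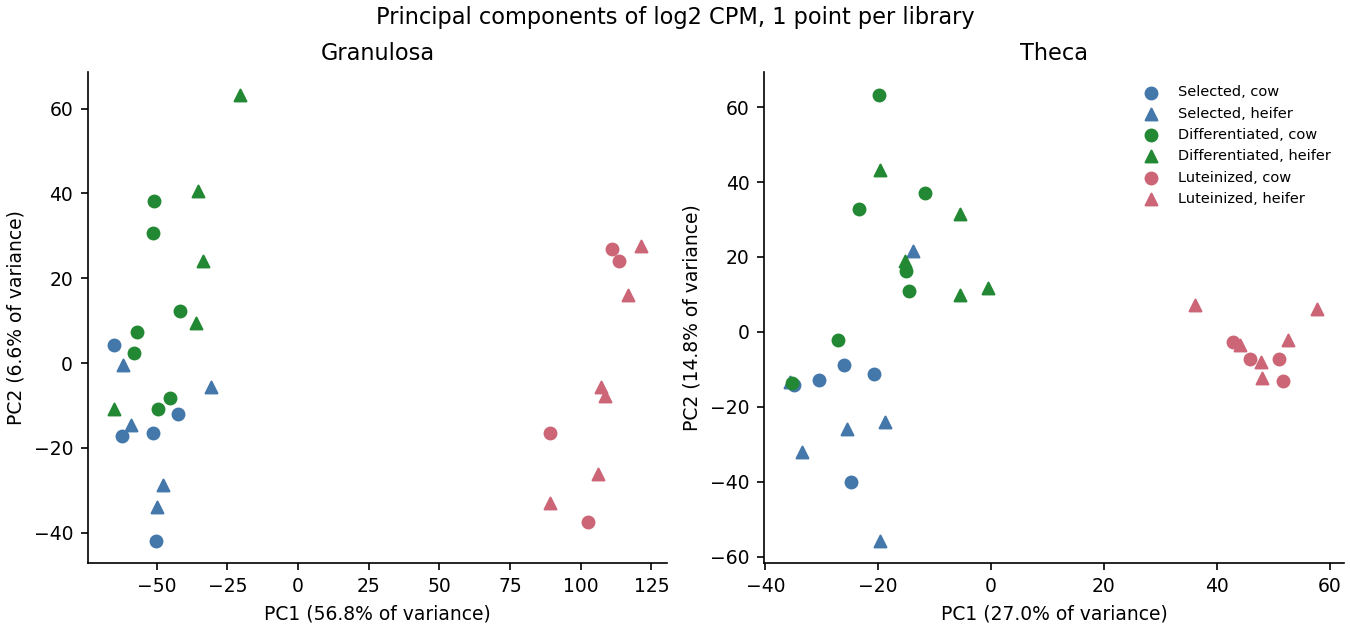
Each point is 1 library, placed by the first and second principal components of log2 CPM in each tissue, without the 559 transcripts near 0 in 6 granulosa libraries; colours give the stage and shapes the animal type. The Luteinized libraries lie apart along the first component, which holds 56.8% of the variance in granulosa and 27.0% in theca.

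Of the 32 granulosa libraries, 6 lacked a common set of transcripts. These were the libraries of cows 677.1, 666.1 and 726.1 and heifers 3563.1, 3701.1 and 3751.1, and each of the 6 granulosa groups held exactly 1 of them. The set was 559 of 14793 transcripts judged (3.78%), each below 0.1 of its expected count over the 6 libraries, and 192 of them had no read there. The set made up 0.0030% to 0.0042% of counts in the 6 libraries, 1.89% to 2.71% in the other 26 and 2.46% to 3.70% in theca. Counts of granulosa calls, of calls between the tissues and of calls shared by both tissues were also taken with these libraries as a covariate, without them and without the 559 transcripts.

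**Figure D2:**
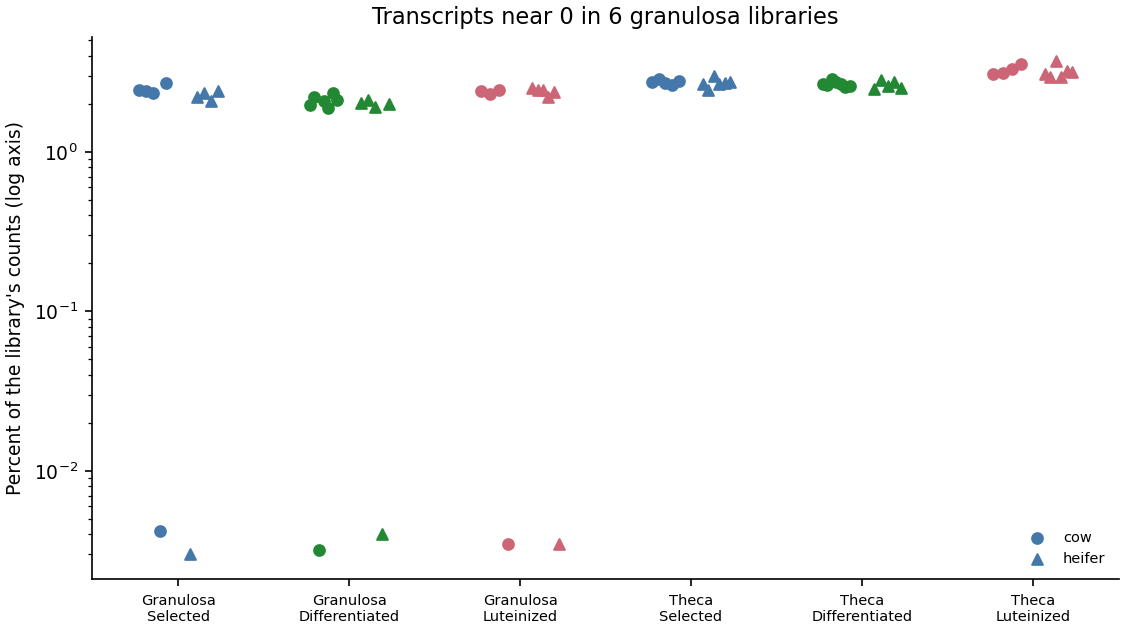
Each point is 1 library, and the vertical log axis gives the percent of its counts that fall on the 559 transcripts near 0 in 6 granulosa libraries. The 6 libraries, 1 per granulosa group, lie at or below 0.0042%, and all others lie at 1.89% or above.

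The change from Selected to Differentiated, when the chosen follicle matures before the gonadotrophin surge, altered 1262 of 14297 granulosa transcripts (8.83%). Of these, 660 rose and 602 fell, and 255 rose and 149 fell by 2-fold or more. The largest rise among named transcripts was that of ENSBTAT00000045669, from 0.0641 ± 0.203 CPM (SD, n = 10) to 2.41 ± 2.09 (SD, n = 12). Only 3 of its reads lay in Selected libraries, and the pooled count ratio was 32.2 with a counting interval of 10.8 to 158 (adjusted p = 0.000204). ENSBTAT00000013014 rose from 0.159 ± 0.214 CPM to 5.37 ± 6.63, a log2 fold change of 5.07 ± 1.02 (SE, adjusted p = 0.00149). ENSBTAT00000020086 fell from 119 ± 148 CPM to 6.45 ± 11.2, a log2 fold change of -4.13 ± 0.83 (adjusted p = 0.00144), and ENSBTAT00000014656 from 116 ± 124 CPM to 10.1 ± 12.9, a log2 fold change of -3.51 ± 0.65 (adjusted p = 0.000673). The count was 1342 with the 6 libraries as a covariate and 1031 without them. Within the 6 libraries alone, with 2 per stage, 1 transcript was called, and 849 of the 979 calls of the other 26 libraries that could be tested there (86.7%) had the same direction.

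Over the same interval, 3192 of 15362 theca transcripts were called (20.8%), 1664 higher and 1528 lower at Differentiated, and 293 rose and 125 fell by 2-fold or more. The median log2 fold change of those that rose was 0.53, against 0.82 in granulosa, a difference that was not tested. ENSBTAT00000046677 rose from 14.1 ± 19.3 CPM (SD, n = 11) to 149 ± 87.3 (SD, n = 12), a log2 fold change of 3.65 ± 0.47 (SE, adjusted p = 3.4e-06). ENSBTAT00000056008, a member of the set lacking in 6 granulosa libraries, rose from 1.78 ± 3.79 to 11.3 ± 7.36 CPM (log2 fold change 3.21 ± 0.47, adjusted p = 1.86e-05). ENSBTAT00000028933 fell from 19.5 ± 22.9 to 2.33 ± 5.14 CPM (log2 fold change -3.72 ± 0.60, adjusted p = 5.35e-05) and ENSBTAT00000044104 from 15.8 ± 18.4 to 1.91 ± 4.06 CPM (log2 fold change -3.71 ± 0.59, adjusted p = 4.71e-05).

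Luteinization, the switch towards progesterone-secreting luteal cells that follows the gonadotrophin surge, altered most of the granulosa transcripts tested. Of 14297 tested, 8011 (56.0%) were called, 3935 higher and 4076 lower at Luteinized than at Differentiated, and 2081 rose and 1912 fell by 2-fold or more. ENSBTAT00000018774 rose from 0.989 ± 1.99 CPM (SD, n = 12) to 1753 ± 795 (SD, n = 10), a log2 fold change of 10.98 ± 0.72 (SE, adjusted p = 7.3e-14). ENSBTAT00000011863 rose from 1.98 ± 2.33 CPM to 1883 ± 922, a log2 fold change of 10.0015 ± 0.58 (adjusted p = 5.95e-15). Some of the most abundant granulosa transcripts were nearly lost. ENSBTAT00000053259 fell from 12054 ± 2369 CPM to 85.3 ± 27.6, a log2 fold change of -7.15 ± 0.29 (adjusted p = 2.35e-18), and ENSBTAT00000019823 fell from 7189 ± 2513 CPM to 12.7 ± 14.6, a log2 fold change of -9.14 ± 0.66 (adjusted p = 5.86e-13). The count was 8239 with the 6 libraries as a covariate and 7594 without them. Within the 6 libraries alone 2446 transcripts were called, and 6943 of 7141 calls of the other 26 libraries (97.2%) had the same direction there.

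In theca, luteinization altered 5009 of 15362 transcripts (32.6%), 2576 higher and 2433 lower, with 620 rises and 490 falls of 2-fold or more. ENSBTAT00000030320 rose from 0.0968 ± 0.137 CPM (SD, n = 12) to 22.4 ± 15.4 (SD, n = 10), a log2 fold change of 7.78 ± 0.48 (SE, adjusted p = 1.95e-13), and ENSBTAT00000018336 rose from 0.269 ± 0.239 to 42.0 ± 9.999 CPM (log2 fold change 7.04 ± 0.27, adjusted p = 4.94e-20). ENSBTAT00000019823, which was nearly lost from granulosa, also fell in theca, from 157 ± 92.7 to 0.115 ± 0.164 CPM (log2 fold change -10.37 ± 0.78, adjusted p = 2.07e-12); its level in Differentiated theca was 2.18% of that in Differentiated granulosa, within the range of the upper bounds on granulosa carried over into these theca libraries (1.55% to 5.66% over 12 animals). ENSBTAT00000046612 fell from 24.4 ± 11.1 to 0.195 ± 0.258 CPM (log2 fold change -6.62 ± 0.44, adjusted p = 1.17e-13).

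**Figure D3:**
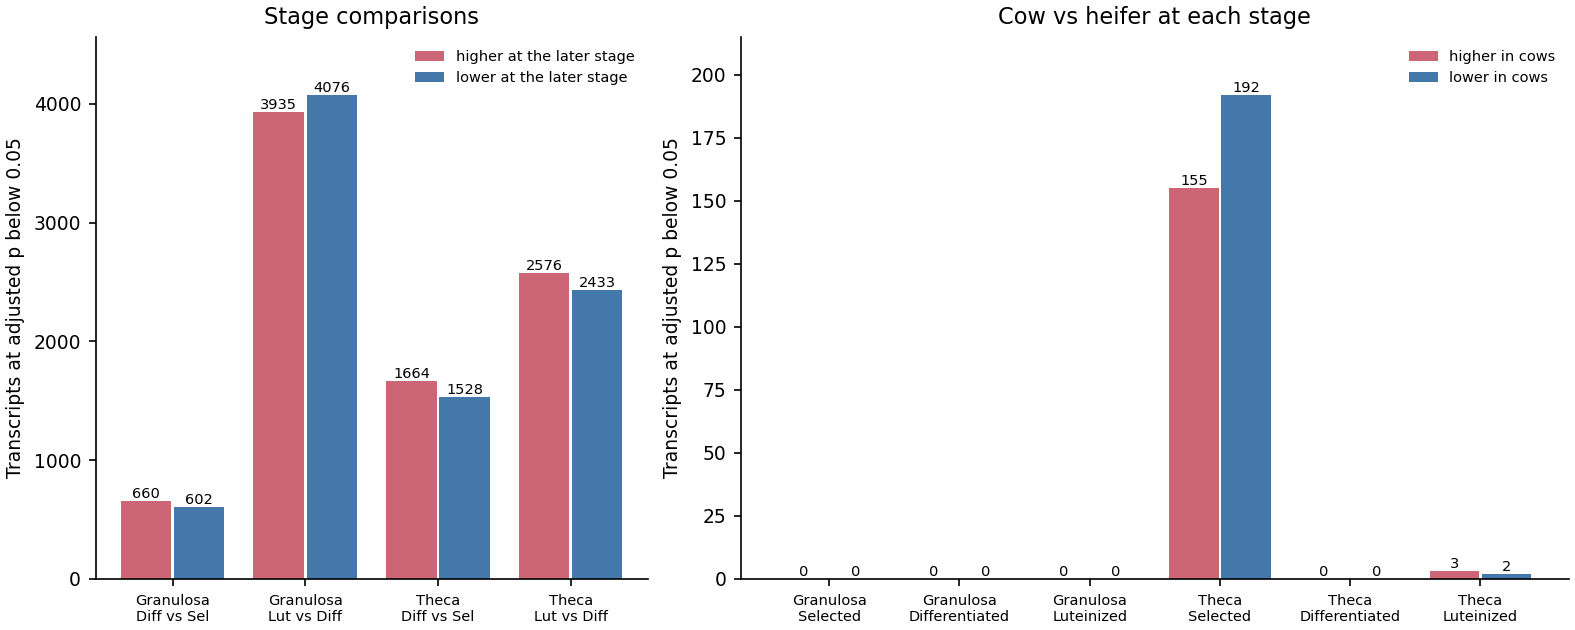
Bars give the number of transcripts at adjusted p below 0.05, higher and lower, for the stage comparisons (left) and for cows against heifers at each stage (right), with the counts printed on the bars and separate vertical scales. Granulosa at luteinization has the most calls, 3935 higher and 4076 lower.

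At luteinization, the changes shared by both tissues mostly had the same direction. Among 13813 transcripts tested in both tissues, 3018 were called in both at luteinization, 1460 higher in both, 1174 lower in both and 384 in opposite directions. Lists of these sizes drawn independently would share 616 higher, 631 lower and 1248 opposite. Because both tissues came from the same animals, the count was repeated with granulosa of some animals and theca of the others. In 2 such draws of 14 granulosa and 19 theca libraries, 1286 of 1361 (94.5%) and 1259 of 1428 (88.2%) transcripts called in both had the same direction. Over all granulosa calls of these draws, theca had the same sign for 80.8% and 67.1%, with Spearman correlations of 0.502 and 0.323. RNA of 1 tissue carried into the other would also give shared directions, in separate animals as well, and its part was not tested. Its upper bounds reached 9.185% in Luteinized theca and 4.90% in Luteinized granulosa libraries. From Selected to Differentiated, 479 transcripts were called in both, 251 higher, 169 lower and 59 opposite, against 69.2, 53.1 and 121 for independent lists. For this step the draws from separate animals gave 4 and 0 granulosa calls, with 2 and 0 transcripts called in both, 0 of them in the same direction, and Spearman correlations of 0.0195 and 0.238 between the log2 fold changes of the tissues, so agreement apart from the shared animals was not shown there.

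Granulosa and theca differed at 12374 of 15801 transcripts (78.3%) averaged over stages, 6047 higher in granulosa and 6327 higher in theca. Which tissue held more calls turned with the setting, with 6669 higher in granulosa and 5957 in theca under animal as a block, 6303 and 5912 without the 559 transcripts, and 6799 and 5753 without heifer 3700. At 2-fold or more, 1679 were higher in granulosa and 3583 in theca. ENSBTAT00000019823 was at 4013 ± 3623 CPM in granulosa (SD, n = 32) and 73.4 ± 90.3 in theca (SD, n = 33), a log2 fold change of 6.13 ± 0.36 (SE, adjusted p = 2.36e-23). ENSBTAT00000011124 was at 14.3 ± 29.6 CPM in granulosa and 0.0797 ± 0.235 in theca (log2 fold change 6.25 ± 0.54, adjusted p = 9.03e-16). ENSBTAT00000018479 was at 2964 ± 1871 CPM in theca and 43.0 ± 56.0 in granulosa (log2 fold change -6.43 ± 0.31, adjusted p = 5.04e-27), and ENSBTAT00000019434 at 13.5 ± 7.43 CPM in theca and 0.105 ± 0.239 in granulosa (log2 fold change -6.94 ± 0.29, adjusted p = 2.49e-28).

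The tissues changed differently between stages. The interaction of tissue with stage was called for 732 transcripts from Selected to Differentiated and for 6384 (40.4%) from Differentiated to Luteinized. Of the 2047 transcripts that were 2-fold or more higher in granulosa at Differentiated, 927 (45.3%) were still so at Luteinized, and 161 were then 2-fold or more higher in theca. Of the 3608 that were higher in theca, 2574 (71.3%) were still so, and 174 were then higher in granulosa. Between Selected and Differentiated the corresponding shares were 75.4% of 2211 and 88.2% of 3656, with 7 and 3 transcripts changing sides. Transcripts called different between the tissues numbered 11174 at Selected, 11021 at Differentiated and 10192 at Luteinized, and 11529, 11447 and 10572 with animal as a block, where 1019 of 2277 (44.8%) stayed higher in granulosa and 2485 of 3497 (71.1%) in theca from Differentiated to Luteinized. The median absolute log2 difference between the libraries of an animal was 0.75 ± 0.10 (SD, n = 12) at Differentiated and 0.73 ± 0.07 (SD, n = 10) at Luteinized, a difference within the spread between animals (permutation test, two-sided, p = 0.577, adjusted p = 0.665). This holds for that measure alone. The Pearson correlation between the libraries of an animal ran from 0.739 to 0.838 at Differentiated and from 0.752 to 0.855 at Luteinized. Its change between stages was not tested.

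Transcripts biased to a tissue at Selected were followed through luteinization. Of 665 granulosa-biased transcripts tested in granulosa, 445 fell, 66 rose and 154 were not called, with a median log2 fold change of -1.38. The set was lower than other transcripts by camera with the preset correlation (adjusted p = 9.4e-23) and with an estimated correlation (adjusted p = 0.000396). Of 1451 theca-biased transcripts, 833 rose, 76 fell and 542 were not called in granulosa, with a median of 1.202. This set was higher with the preset correlation (adjusted p = 3.88e-18) but not with an estimated correlation (adjusted p = 0.175). The filter on low counts, which a rise at Luteinized helps a transcript to pass, had left out 1018 of the 2469 theca-biased and 14 of the 679 granulosa-biased transcripts. With no filter, 988 of 2467 theca-biased transcripts rose and 113 fell (median 0.83, adjusted p = 8.48e-13, and 0.179 with an estimated correlation), and 445 of 679 granulosa-biased ones fell and 65 rose (median -1.37, adjusted p = 4.93e-25, and 9.65e-05 with an estimated correlation). With a filter on the Selected libraries alone, 376 of 670 theca-biased transcripts rose and 53 fell (median 0.93). Without the 6 libraries the medians were 1.22 and -1.38. In theca, the granulosa-biased set had 92 rises and 140 falls among 495 members (median -0.09, adjusted p = 0.177, and 0.756 with an estimated correlation), and the theca-biased set 733 rises and 372 falls among 2445 (median 0.15, adjusted p = 0.00213, and 0.206 with an estimated correlation). From Selected to Differentiated, with sets chosen at Luteinized, the granulosa-biased set rose in granulosa, with 94 rises and 42 falls among 592 (median 0.27, adjusted p = 0.000126, and 0.112 with an estimated correlation; with no filter, 84 rises and 35 falls among 609, adjusted p = 5.51e-05, and 0.0474 with an estimated correlation, which gave 0.0555 with a filter on the Luteinized libraries alone and 0.06997 without the 6 libraries).

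**Figure D4:**
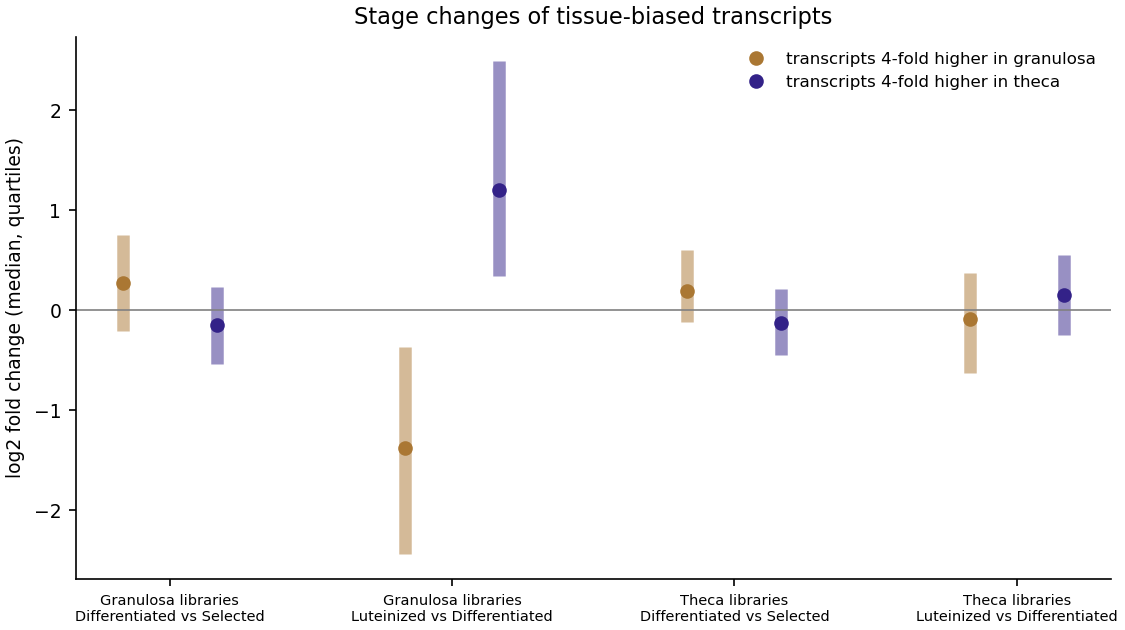
Points give the median and bars the quartiles of the log2 fold changes of transcripts 4-fold or more higher in granulosa or in theca, in granulosa and theca libraries for each stage comparison; each set was chosen at the stage outside the comparison. The widest movement is in granulosa at luteinization, with medians of -1.38 and 1.202.

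The most abundant transcripts took a smaller share of granulosa counts at luteinization and a larger share of theca counts. The 10 most abundant transcripts held 14.6% ± 2.05 of counts in Differentiated granulosa (SD, n = 12) and 7.61% ± 0.770 in Luteinized granulosa (SD, n = 10), with no overlap between libraries (11.4% to 17.8% against 6.27% to 9.08%; permutation test, two-sided, adjusted p = 0.0001, from the smallest p the resamples can give). Without the 6 libraries the means were 14.5% and 7.47%, and among the 6 the values were 14.9% and 15.0% against 7.34% and 9.08%. In theca the share was 11.4% ± 1.31 (SD, n = 12) at Differentiated and 14.4% ± 1.89 (SD, n = 10) at Luteinized (permutation test, adjusted p = 0.0027). At a common depth, 14557 ± 324 transcripts were detected in Differentiated and 14922 ± 284 in Luteinized granulosa (permutation test, adjusted p = 0.0311), and 15564 ± 137 and 15700 ± 60.8 in theca (permutation test, adjusted p = 0.0265). Selected and Differentiated libraries differed by less than the spread between animals in the top 10 share, at adjusted p = 0.112 in granulosa and 0.646 in theca by the same permutation tests.

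**Figure D5:**
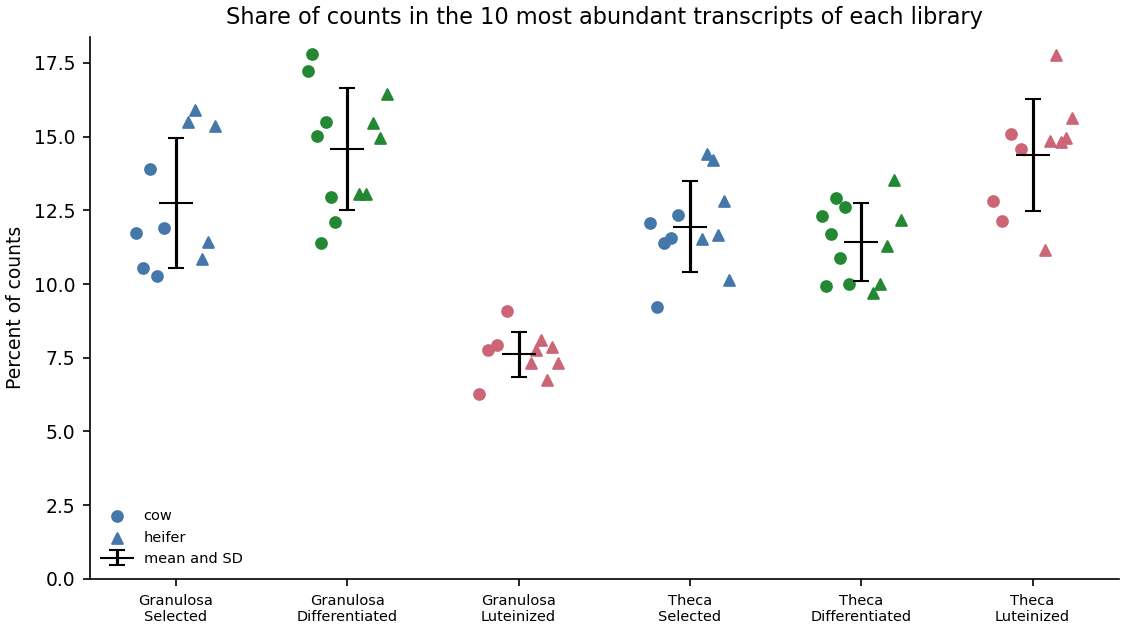
Each point is 1 library, and the vertical axis gives the percent of its counts in its 10 most abundant transcripts, by tissue and stage, with means and SD as bars. Luteinized granulosa libraries lie between 6.27% and 9.08%, below every Differentiated granulosa library.

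Cows and heifers were compared within each tissue to ask whether lactating animals differ in the dominant follicle. In granulosa, edgeR called 0 of 14297 transcripts at Selected, at Differentiated, at Luteinized and averaged over stages, with 730, 558, 399 and 709 at an unadjusted p below 0.05. DESeq2 called 19, 1, 1 and 2. The interaction of animal type with stage also gave 0 calls, with 453 at an unadjusted p below 0.05 and 0 by DESeq2. The simulated comparison at Selected recovered 25 of 50 changes of 2-fold and 46 of 50 of 4-fold at these group sizes. The simulation drew transcripts independently and changed only those above a minimum level, so recovery in the real libraries may be lower.

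Theca transcripts were called different between cows and heifers at Selected. Of 15362 transcripts, 347 were called, 155 higher and 192 lower in cows, and 56 and 126 of these differed by 2-fold or more. Which direction held more calls depended on the setting, with 327 higher and 268 lower under the number suffix as a covariate, 424 and 348 without heifer 3700, 344 and 266 without cow 610.1, and 7 and 28 with only the Selected libraries in the fit. ENSBTAT00000004444 was at 15.8 ± 7.67 CPM in cows (SD, n = 5) and 164 ± 242 in heifers (SD, n = 6), and every heifer library (48.1 to 657 CPM) lay above every cow library (7.39 to 26.3 CPM), a log2 fold change of -3.34 ± 0.65 (SE, adjusted p = 0.00489). ENSBTAT00000027940 was at 31.1 ± 8.07 CPM in cows and 9.19 ± 9.61 in heifers (log2 fold change 1.88 ± 0.34, adjusted p = 0.00233), and ENSBTAT00000017239 at 9.99 ± 5.70 and 2.85 ± 1.41 (log2 fold change 1.72 ± 0.39, adjusted p = 0.0166). The mean of ENSBTAT00000011146 was 1.23 ± 0.653 CPM in cows and 17.1 ± 35.9 in heifers (log2 fold change -3.71 ± 0.89, adjusted p = 0.0248), but without heifer 3757.1 its log2 fold change was -1.03 (adjusted p = 0.327). It also lost its call without cow 566.1, 677.1 or 710.1 (adjusted p 0.0515 to 0.0817), with log2 fold changes of -3.56, -3.58 and -4.19. ENSBTAT00000017239 lost its call without cow 566.1 or 710.1 (adjusted p = 0.0521 and 0.0566), with log2 fold changes of 1.60 and 1.63. The count of 347 depended on single animals: it was 82 without cow 677.1, 107 without cow 710.1, 159 without cow 566.1, 168 without heifer 3703.1, 183 without heifer 3563.1 and 186 without heifer 3568, and rose to 610 without cow 610.1, 686 without heifer 3757.1 and 772 without heifer 3700. With only the theca libraries of Selected in the fit it was 35, and none of the 4 transcripts was then called, their adjusted p running from 0.0811 to 0.21. Their log2 fold changes in that fit were -3.34 (ENSBTAT00000004444), 1.89 (ENSBTAT00000027940), 1.73 (ENSBTAT00000017239) and -3.71 (ENSBTAT00000011146).

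At the later stages few theca differences were called. At Differentiated, edgeR called 0 transcripts, with 1574 at an unadjusted p below 0.05, and DESeq2 called 5. At Luteinized, 5 transcripts were called, 3 higher and 2 lower in cows, and 3 of them reached the expression set for naming. ENSBTAT00000038349 was at 46.7 ± 16.5 CPM in cows (SD, n = 4) and 17.4 ± 5.46 in heifers (SD, n = 6), a log2 fold change of 1.39 ± 0.22 (SE, adjusted p = 0.00378). ENSBTAT00000017935 was at 85.3 ± 6.13 and 141 ± 25.2 CPM (log2 fold change -0.75 ± 0.13, adjusted p = 0.0148) and ENSBTAT00000020308 at 31.7 ± 7.24 and 54.0 ± 6.25 CPM (log2 fold change -0.79 ± 0.16, adjusted p = 0.0456). The count was 0 without cow 718.1, 3 without each of cows 623.1, 681.1 and 726.1 and heifer 3710.1, and 0 in a fit of only the Luteinized theca libraries. ENSBTAT00000038349 lost its call without cow 718.1 (adjusted p = 0.0954), ENSBTAT00000017935 without any of 6 animals (0.0515 to 0.18) and ENSBTAT00000020308 without any of 8 (0.0656 to 0.536). Averaged over stages, 127 transcripts were called, 24 higher and 103 lower in cows, of which 77 were also called at Selected. ENSBTAT00000004444 was again among them (51.7 ± 32.7 CPM in 16 cows and 132 ± 156 in 17 heifers, log2 fold change -1.65 ± 0.35, adjusted p = 0.0127), with ENSBTAT00000037578 (2.61 ± 2.15 and 7.66 ± 4.83 CPM, log2 fold change -1.66 ± 0.38, adjusted p = 0.0249) and ENSBTAT00000004331 (14.3 ± 5.00 and 9.01 ± 3.32 CPM, log2 fold change 0.76 ± 0.16, adjusted p = 0.0121). Without heifer 3701.1 the count was 82, and ENSBTAT00000037578 had an adjusted p of 0.0573. ENSBTAT00000012973 (10.1 ± 6.52 and 4.98 ± 3.18 CPM, log2 fold change 1.10 ± 0.27, adjusted p = 0.0413) lost its call when any 1 of 20 animals was left out (adjusted p 0.0518 to 0.11).

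Whether the cow and heifer difference in theca changed with stage was tested directly. The interaction gave 0 calls in edgeR, with 2256 transcripts at an unadjusted p below 0.05 and a smallest adjusted p of 0.0518, and 183 calls by the likelihood ratio test of DESeq2. It gave 40 calls without heifer 3757.1. The 347 transcripts called at Selected had the same direction in 229 cases (66.0%) at Differentiated and in 200 (57.6%) at Luteinized, in other animals, against 49.5% and 48.4% of all transcripts tested. Those higher in cows at Selected (median log2 fold change 0.817) had medians of 0.0758 at Differentiated and -0.0434 at Luteinized. Those lower in cows (median -1.196) had medians of -0.224 and -0.142. The transcripts were chosen for their difference in the Selected libraries, which enlarges the medians there. Smaller medians in other animals therefore do not show that the difference changed with stage. In granulosa at Selected, from the same animals apart from heifer 3700, 245 of 288 (85.1%) had the same direction, against 61.3% of all transcripts tested, and 0 were called.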

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

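The tests on the 6 granulosa libraries, on theca-biased calls and on the fall of granulosa-biased transcripts, the use of all members of a set with no filter, the ratios within animals and the sets chosen at later stages were chosen after the results were seen.

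Over 12 groups and 4 measures, which make 48 comparisons, 8 values stood apart from their group, where chance gives about 1 in 20. Of these, 7 concerned the share of counts in the 559 transcripts lacking in part of the granulosa libraries, and 6 of the 7 follow from how these transcripts were chosen, so they are not evidence of their own. The share was 0.00417% in Selected cow 677.1, 0.0030% in Selected heifer 3563.1, 0.00321% in Differentiated cow 666.1, 0.00401% in Differentiated heifer 3701.1, 0.00348% in Luteinized cow 726.1 and 0.00348% in Luteinized heifer 3751.1. Among the theca libraries of Luteinized heifers the share was highest in heifer 3702, at 3.70% against 3.21% in the next, while Luteinized cow 726.1 had 3.54%. Among the granulosa libraries of Selected heifers, heifer 3568 had 15433 transcripts detected at a common depth (15433.3), against 14476 in the next, while Luteinized cow 623.1 had 15390.

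The loss of 559 transcripts from 6 granulosa libraries was not explained by shallow sequencing, since the 6 had a median total of 5446780 counts against 3923200 in the other 26. It was not a property of the animals shared by both tissues, because theca of the same 6 animals held these transcripts at a median ratio of 1.005 to the other theca libraries. It did not follow the study groups, as 6 of 6 granulosa groups held exactly 1 such library. Of 409 transcripts with an expected count of at least 20 in each of the 6 libraries, 99.3% were under 0.2 of that count in all 6. The set was chosen for a pooled count below 0.1 of the expected over these same libraries. The choice therefore largely fixed this share, and it does not test a cause. A difference in processing shared by these libraries, such as another annotation or transcript list, remains possible. A property of the granulosa of these animals alone was not tested, and the cause of the loss stays open.

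The response to stage differed between granulosa and theca, with 732 interaction calls from Selected to Differentiated and 6384 from Differentiated to Luteinized. Chance assignment of animals to stages was unlikely for both but not excluded. In each case 1 of 60 splits, the real one, gave as many calls, the smallest share these splits can give. The highest of the other splits gave 420 and 900, and no correction was made for the number of comparisons split.

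In granulosa at luteinization, 445 of 679 granulosa-biased transcripts fell and 988 of 2467 theca-biased transcripts rose with no filter on low counts. Theca tissue carried into the granulosa libraries did not account for the fall, whose median needed 61.4% carry-over against a bound of 2.11%, the 5th percentile of the granulosa-to-theca ratios of 359 abundant theca-biased transcripts; for the rise it remained undecided, since the median over all 2469 members needed 4.31%, which is 2.04 times that bound (1.56 to 3.46 over resampled animals) and not clear of the 2 times set beforehand, while within animals, each with its own bound (median 1.21%), the ratio had a median of 2.80 and was above 2 in 8 of 10 animals (-0.212 and 1.77 in the others). The rise did not rest on the 50 most abundant granulosa transcripts: without them the median log2 fold change of theca-biased transcripts was 0.815, against 0.835 with them. TMM sets extreme transcripts aside, so this check was bound to move little. It cannot exclude that depth freed by the loss of abundant granulosa transcripts contributed to the rise. Regression to the mean from chance error in the Differentiated libraries was argued against by sets chosen at Selected, outside the comparison. Their median was 0.968 of that of sets chosen at Differentiated. Both choices precede luteinization, so this check cannot exclude that transcripts chosen as extreme moved back within a broad change of granulosa. A biological loss of granulosa-biased transcripts at luteinization may be a hypothesis to follow up, found and tested on the same data. No granulosa marker could be examined without gene names, so a loss of granulosa identity was not tested. The rise of theca-biased transcripts was not called as a set by camera with an estimated correlation (adjusted p = 0.179). Cells of further types were not tested and stay open.

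The 347 cow and heifer calls in theca at Selected were weighed against 3 technical explanations. The suffix of the animal number as a batch did not account for them, as 304 of the 347 (87.6%) were still called with it as a covariate, in the same direction, among 595 calls. Granulosa carried over into theca remained undecided as a whole, the share of granulosa-biased transcripts among the calls being 1.25 times that among all tested for sets chosen at Selected, 1.11 times at Differentiated and 0.706 times at Luteinized, resting on 14, 11 and 6 calls; yet it would dilute theca-biased transcripts alike, and of 137 such calls 47 were higher and 90 lower in cows (41 and 115 for sets chosen at Differentiated). Depth may contribute: thinning every theca library to the smallest total left a median of 35 of the 347 calls over 5 draws (31 to 46), while thinning each by an equal share left 143 (135 to 158), although totals of cows (3526722 to 9561195) and heifers (2366057 to 8736573) overlapped. Chance was not clearly excluded. Of 100 splits, 4 gave as many calls, the real one included. This met the limit of fewer than 5 set beforehand, but the highest of the others gave 773. The count also ran from 82 to 772 with 1 animal left out, and no correction was made for the number of comparisons split. Lactation or age, which differ between cows and heifers, remain possible and untested explanations.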

How the results depend on the processing

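The 6 libraries as a covariate, their omission, the omission of the 559 transcripts, that of heifer 3700 and all alternatives for the tissue-biased sets, the tissue calls at each stage and the shared calls were chosen after seeing the data. Of 118 counts of calls under other settings, 101 stayed within 1.5 times the reported count, and 17 did not; all 17 concerned cows against heifers. The stage and tissue comparisons stayed within 1.5 times under every setting run and every animal left out. DESeq2 gave 19, 1, 1 and 2 calls for granulosa cows against heifers at Selected, Differentiated, Luteinized and averaged over stages, and 700, 5, 8 and 220 in theca, with 183 for the theca interaction of animal type with stage. With the number suffix as a covariate there were 2 granulosa calls and 595 theca calls at Selected and 1 for the theca interaction, which also had 1 call without a filter and 1 without heifer 3700. Fitting only the groups compared gave 35 theca calls at Selected and 0 at Luteinized, with fewer samples to estimate the spread, and omission of heifer 3700 gave 772 at Selected. The causes of the other changes were not tested.

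Leaving out each animal in turn gave 0 to 6 granulosa calls at Selected, 0 to 1 at Luteinized and 0 to 1 averaged over stages. In theca it gave 82 to 772 at Selected, 0 to 5 at Luteinized, 82 to 153 averaged over stages and 0 to 40 for the interaction. The stage counts ran from 960 to 1475 and 7651 to 8128 in granulosa and from 2641 to 3875 and 4433 to 5127 in theca. With animal as a block over the 32 animals with both tissues, 12626 transcripts were called between granulosa and theca, 1087 for the interaction of tissue with stage from Selected to Differentiated and 6652 from Differentiated to Luteinized, so the block moved no count by over 1.5 times. Without the 6 libraries the theca-biased set changed direction in granulosa from Selected to Differentiated, from a median of -0.15 to 0.0888. With an estimated correlation 5 of 8 sets were no longer called (in granulosa, medians 0.272 from Selected to Differentiated and 1.202 at luteinization, adjusted p 0.112 and 0.175; in theca, medians 0.194, -0.129 and 0.149, adjusted p 0.175 to 0.206), and with a filter on Selected alone the granulosa-biased set fell in theca at luteinization (median -0.151, adjusted p = 0.000551), though not with an estimated correlation (adjusted p = 0.363).

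Of 205 values of named transcripts under other settings, 196 kept their call, 9 lost it and 0 changed direction; with animals left out, 652 of 694 kept it, 42 lost it and 0 changed direction. The losses fell on 9 named transcripts, all from theca cow and heifer comparisons. Other splits of the same libraries into stages gave at most 10 and 2019 calls in granulosa and 1402 and 1649 in theca. For each, only the real one of 100 splits was as large, the smallest share these splits can give. Chance was therefore an unlikely source of the stage counts of 1262, 8011, 3192 and 5009, without correction for the number of comparisons split. Swapping the tissue labels within animals gave at most 3676 calls, against 12374 (1 of 60 splits). For theca cows against heifers, 2 of 100 splits reached the 5 calls at Luteinized, with a highest of 5, and 1 of 100 the 127 averaged over stages, with a highest of 88. Where the real split gave 0 calls, all 100 of 100 splits gave as many, as any split must, so the splits decide nothing there; single other splits gave up to 676, 8, 1135 and 53 calls in granulosa at Selected, Differentiated, Luteinized and averaged, 605 for its interaction, 21 in theca at Differentiated and 147 for its interaction, so the libraries hold structure that is not animal type. Depth limits what can be called in theca at Selected, where a median of 143 of the 347 calls was kept with each library thinned by an equal share. The alternatives planned for the gene lists (an estimated correlation and fry) were not run, because the transcripts had no gene names here.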

Other observations

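The stage outside each comparison allowed tissue bias to be followed in theca as well. From Selected to Differentiated, the transcripts biased to theca at Luteinized had 490 falls and 190 rises among 2111 in theca (median log2 fold change -0.13, adjusted p = 0.000221, and 0.175 with an estimated correlation), while granulosa-biased transcripts had 83 rises and 18 falls among 376 (median 0.19, adjusted p = 2.98e-05, and 0.206 with an estimated correlation). In granulosa, the theca-biased set had 47 rises and 45 falls among 1141 (median -0.15, adjusted p = 0.996, and 0.999 with an estimated correlation), and without the 6 libraries 62 rises and 29 falls among 1136 (median 0.0888, adjusted p = 0.0255, and 0.572 with an estimated correlation).

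The least shared abundant transcripts of the other tissue bound how much of it each library can hold. In theca libraries, the 5th percentile of the ratios of abundant granulosa-biased transcripts to their level in granulosa of the same animal had a median of 1.33% at Selected, 2.86% at Differentiated and 4.48% at Luteinized. In granulosa libraries, the corresponding value for theca-biased transcripts was 0.493%, 0.818% and 1.21%, with single libraries up to 5.82%. Transcript ENSBTAT00000019823, among the most abundant in Differentiated granulosa at 7189 CPM, stood at 157 CPM in Differentiated theca and fell in both tissues at luteinization.

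The theca calls between cows and heifers at Selected held 137 theca-biased transcripts, as chosen at Selected, among 347 (39.5%), against 2445 of 15362 tested (15.9%), and 156 as chosen at Differentiated, against 2285 tested.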
